A study of Mus musculus with 11 samples.

How the data were processed

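Total RNA from mouse JB6 cells was labelled with biotin and hybridised to Affymetrix oligonucleotide arrays, 1 sample per array, in 4 groups: bFGF-JB6 monolayer (3), bFGF-JB6 colonies (3), RT101 monolayer (2) and RT101 colonies (3). Groups, replicate numbers and doses came from the submitters' titles, source names and descriptions. The deposited table holds log2 signals per probe set that the authors made with RMA, per the submitters' processing notes, which give no version. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of each probe set; it gives no detection calls and compresses folds of weak signals. How the images were scanned and which settings were used is not given in the sources used here. The values were used as deposited, with no further scaling or filter on low values. There are no counts behind array signals, and the number of arrays limits the precision.

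Of 22690 probe sets, 64 were controls, 20380 named a single gene symbol in the platform annotation, 691 named several and 1555 named none. By their gene number 20351 of the single-gene probe sets were found in the reference gene table and 29 were not; no symbol changed. Each of 12393 genes was represented by its brightest single-gene probe set over all 11 arrays, and 4956 genes had more than 1. Genes were named only from such probe sets. Members of fixed lists without one were not analysed here. Probe sets of gene families with near-identical sequences, for example those of Oas, Gst, Klra and beta protocadherin genes, can read several members, and their values are uncertain. For the genes named here, other probe sets of Higd1a and Notch4 were called opposite to the brightest.

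Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 11 arrays at once, with group as the only term, and variances were moderated by eBayes (7 residual and 6.12 prior degrees of freedom). Contrasts were colonies against monolayer within each line, the difference between these changes, and RT101 against bFGF-JB6 in monolayers and in colonies. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 over the 12393 genes, with the counts at a 2-fold change beside them; SE is the moderated standard error on the log2 scale. Shared calls were set against n1 × n2 / N for independent lists, with two-sided Fisher's exact tests. For 32 gene lists, including markers of macrophages, endothelial cells, adipocytes, skeletal muscle and melanocytes, limma's camera compared members with all other genes at a preset correlation of 0.01, adjusted over the lists within a contrast. It was repeated with a correlation estimated for each list. Median, mean and test of a list differed in sign only among lists that did not pass in the contrast concerned, such as hypoxia genes in RT101 colonies.

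Design, lists and the rule for naming genes were set before the data were examined. The rule took, in each colony comparison, the 10 genes with the largest increase and the 10 with the largest decrease among those called whose colony arrays all lay on one side of all monolayer arrays, and up to 4 called members of each list. It took 8 genes per direction for both comparisons and for the difference between lines, 10 per direction between lines, and always Fgf2, Fgfr1, Cdkn1a, Ccnd1, Vim and Cdh1. Ptprc was named outside it, after its values were seen.

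The procedure was tested on simulated data made from the 12393 genes' own means and spreads, with 200 genes changed. For the bFGF-JB6 colony contrast it recovered 78% of changes of 0.5 on the log2 scale and 100% of changes of 1, with 8 false calls among 197. For RT101 colonies it recovered 72% and 98%, and for the difference between lines 18% and 94%, so the simulation often missed small differences. Only 200 genes changed there, which made the adjusted p stricter than in the data, where 3430 genes passed for this difference. These shares therefore need not hold in the data. A list shifted on purpose was found and 0 of 32 unchanged lists were called. Genes were simulated independently of each other, so this says nothing about false calls among lists of correlated genes. In the data the correlation estimated for a list reached 0.204 (macrophage markers).

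Alternatives set beforehand were a replicate block from the titles or from the letters in the descriptions, the mean of a gene's probe sets, all probe sets tested separately, genes above the median level, median centring, cyclic loess, a trended robust variance, array weights, a fit of only the groups compared, a 2-fold minimum, the estimated correlation and leaving out each array in turn. Leaving out the 2 arrays with raised 3' signal was added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.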

Results

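The experiment measured messenger RNA on Affymetrix oligonucleotide arrays in mouse JB6 cells, an epidermis-derived line used to study the step from attached to anchorage-independent growth. JB6 clone 41-5A cells, labelled as treated with basic fibroblast growth factor (bFGF), were set beside RT101 cells, a tumorigenic variant of JB6 that received no growth factor. Each kind of cell was sampled as an attached monolayer and as colonies taken from soft agar on day 7. The dose given for bFGF-treated cells in agar was 10 ng/ml; no dose or time was given for the monolayers labelled as treated, so exposure may differ between them and the colonies. There were 3 arrays of bFGF-JB6 monolayer, 3 of bFGF-JB6 colonies, 2 of RT101 monolayer and 3 of RT101 colonies, 11 in all. Array medians ran from 5.82 to 5.95 on the log2 scale and lower quartiles from 3.78 to 3.91. Signals at or below that quartile are near the bottom of the scale, and folds that start or end there are compressed. Arrays of one group correlated at 0.989 to 0.998 across the 22626 probe sets that were not controls, and arrays of different groups at 0.9345 to 0.983. The labels do not say whether arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. On 2 arrays the Gapdh control signal at the 3' end stood further above that at the 5' end than on the other 9 arrays: bFGF-JB6 monolayer replicate 1 (log2 difference 0.19) and bFGF-JB6 colonies replicate 3 (0.35), against -0.08 to -0.01 elsewhere. The series set colonies against monolayers of the same cells to find expression changes shared by reversible (bFGF-driven) and irreversible (RT101) growth in soft agar.

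In bFGF-JB6 colonies the chemokine gene Cxcl12 rose most, from a log2 signal of 5.95 ± 0.13 to 10.78 ± 0.05 (SD, n = 3 each), which is 28.5-fold (SE 0.08 on the log2 scale, limma adjusted p = 4.56e-13). Mgp, which encodes a matrix protein that inhibits calcification, rose 24.1-fold (SE 0.16, adjusted p = 2.24e-10), and the acute-phase gene Saa3 rose 18.9-fold (SE 0.08, adjusted p = 6.96e-13). Other large increases were those of the iron exporter gene Slc40a1 (log2 change 3.70), the protease inhibitor gene Serpina3n (3.69), the dermatopontin gene Dpt (3.48) and the collagenase gene Mmp13 (3.23). Akr1c14 (4.23), Gsta3 (3.67) and Klra17 (3.95) also rose, but belong to families with close relatives, so their probe sets may read more than one gene. The largest falls were those of 2 epithelial cytokine genes. Il33 went from 10.71 ± 0.04 to 5.91 ± 0.04 (SD, n = 3), a log2 change of -4.80 (SE 0.11, adjusted p = 3.5e-12), and Tslp changed by -4.28 (SE 0.11, adjusted p = 1.96e-11). Interferon-induced genes followed, with Ifi27l2a at -3.73, Oas2 at -3.18, Oasl2 at -2.93 and Rtp4 at -2.93. Mndal (-3.45) and Mmp1a (-3.01), both with close relatives, Ggct (-3.15) and the mesothelin gene Msln (-2.79) completed the 10. In all, 3642 of 12393 genes passed an adjusted p of 0.05, 1751 up and 1891 down; 203 rose and 229 fell by at least 2-fold.

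Genes of cell division fell together in these colonies. All 22 measured mitosis genes fell, with a median log2 change of -1.14 (camera adjusted p = 4.03e-22), among them the kinetochore motor gene Cenpe (-2.24), the mitotic kinase gene Aurkb (-1.86) and the cyclin gene Ccnb2 (-1.67). Of 22 DNA replication genes 20 fell (median -0.62, adjusted p = 4.41e-12), including Rrm2, a ribonucleotide reductase subunit (-1.47), and Ccne2, cyclin E2 (-1.25). Of 22 genes induced through ERK or in the immediate early response 16 fell (median -0.69, adjusted p = 1.18e-08), with Hbegf, an EGF receptor ligand, at -2.56, the cyclin D1 gene Ccnd1 at -1.68, Dusp6, an ERK phosphatase, at -1.34 and Fos at -1.34. Interferon-stimulated genes fell as a list (12 down, 4 up of 20; median -0.76, adjusted p = 1.67e-05), with Bst2 at -1.81 and Gbp3 at -1.60. All 4 of these calls held with an estimated correlation between genes (adjusted p 0.00761 to 0.00869). Adjusted over the list alone, 22, 21, 16 and 13 members fell and 0, 0, 1 and 4 rose.

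Lysosome and autophagy genes rose in bFGF-JB6 colonies, 13 of 19 with none down (median 0.66, adjusted p = 2.03e-07; 0.00869 with an estimated correlation). They included Gabarapl1, an autophagosome protein (1.15), the lysosomal channel gene Mcoln1 (1.14) and the sialidase gene Neu1 (1.01). Collagen and matrix genes rose by the preset test (16 up, 3 down of 28; median 0.38, adjusted p = 0.00033) but not with an estimated correlation (adjusted p = 0.173). Lox, a collagen cross-linking enzyme (3.06), Postn, periostin (2.63), and the collagen VI chain genes Col6a1 (2.33) and Col6a2 (2.31) led that list. Targets of NRF2, the regulator of the oxidant response, rose (9 up, 3 down of 18; adjusted p = 0.00172), as did genes of the ATF4 and amino acid response (10 up, 1 down of 24; adjusted p = 0.00268) and of hypoxia (8 up, 3 down of 17; adjusted p = 0.0426), while cholesterol synthesis genes fell (7 down, none up of 18; adjusted p = 0.00818). None of these last 4 passed with an estimated correlation, where the adjusted p were 0.173, 0.173, 0.184 and 0.179. The hypoxia call was also lost without the 2 arrays of raised 3' signal (adjusted p = 0.0546), without monolayer replicate 3 (0.0569) and without colonies replicate 3 (0.0553). Among its members Ndrg1 rose by 1.35, and Higd1a stood at -0.61 on its brightest probe set while 2 other probe sets of the gene were called in the opposite direction. Adjusted over the list alone, lysosome genes gave 13 up and 0 down, matrix genes 17 and 3, NRF2 targets 10 and 3, ATF4 genes 12 and 2, hypoxia genes 11 and 3, and cholesterol genes 1 and 8.

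The other 22 lists did not pass in bFGF-JB6 colonies. Matrix proteases moved both ways (8 up, 5 down of 18; adjusted p = 0.092), with the gelatinase gene Mmp2 at 2.26 and the inhibitor gene Timp1 at -1.77. Cytokine and NF-kB genes did likewise (7 up, 8 down of 25; adjusted p = 0.961). Integrin and adhesion genes had 3 up and 6 down of 20 (adjusted p = 0.067), with the laminin receptor gene Itga6 at -1.78 and the caveolin gene Cav1 at -1.44. For markers of other cell types the adjusted p were 0.164 for macrophage, 0.87 for endothelial, 0.784 for adipocyte, 0.985 for skeletal muscle and 0.131 for melanocyte. Among 13 macrophage markers, Cd68 rose by 1.86 and Csf1r by 0.92, while Lyz2, at 0.36, lost its call without any of 3 single arrays (adjusted p 0.0674 to 0.094). The leukocyte gene Ptprc lay near the bottom of the scale in monolayers and colonies (2.51 and 2.53). The FGF receptor gene Fgfr1 rose by 1.36 (adjusted p = 2.93e-05). Fgf2, which encodes bFGF itself, was at 0.16 (adjusted p = 0.624) and Cdh1, E-cadherin, at 0.06 (adjusted p = 0.64), the latter from signals near the bottom of the scale. Vim, vimentin, was at -0.29 (adjusted p = 0.0128; 0.0602 without monolayer replicate 3) and Cdkn1a, a cell cycle inhibitor gene, at -0.27 (adjusted p = 0.0167; 0.0625 without monolayer replicate 1).

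**Figure D1:**
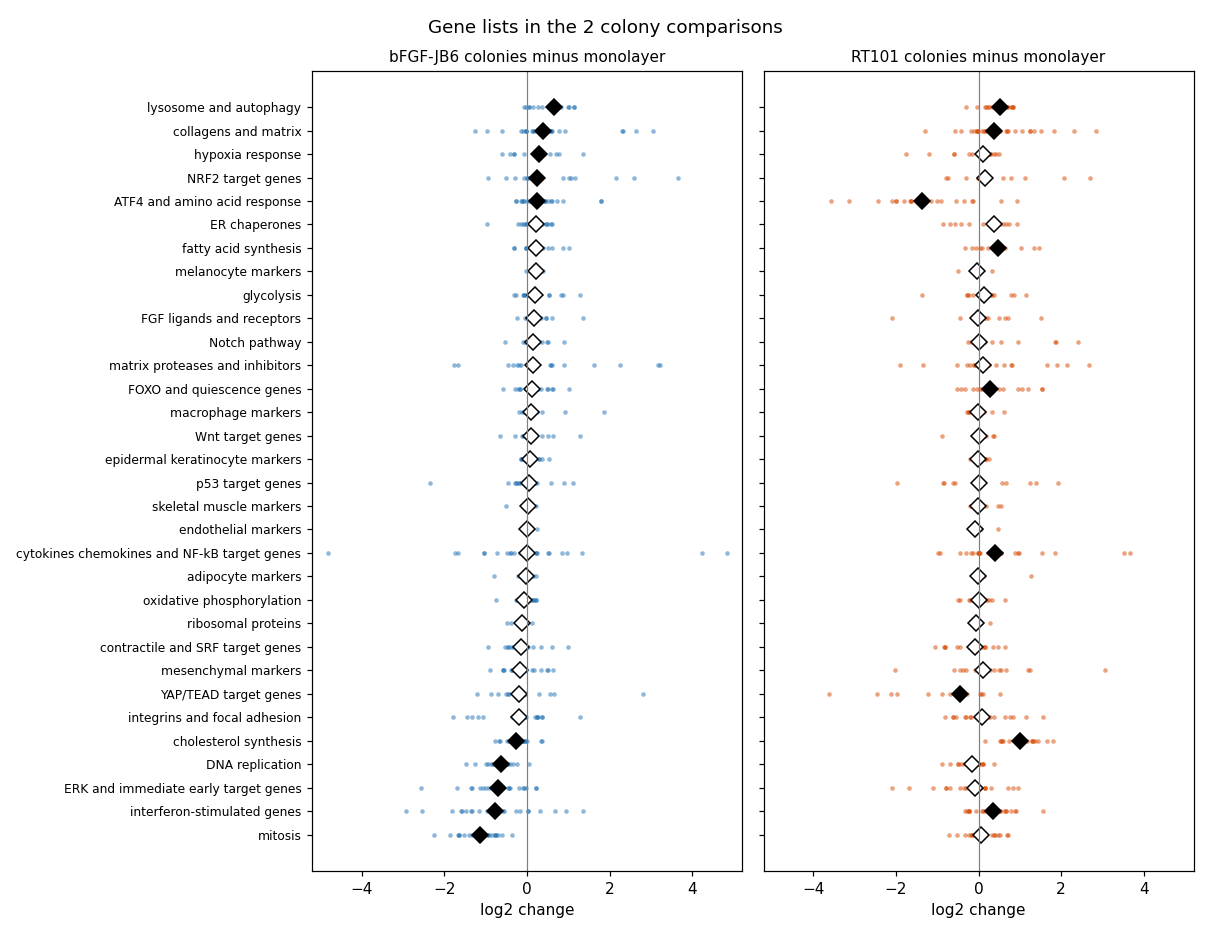
Each small point is the log2 change of 1 gene in colonies against monolayer, bFGF-JB6 on the left and RT101 on the right, for the 32 gene lists fixed beforehand. Diamonds mark the list medians, black where the camera test passed an adjusted p of 0.05; mitosis genes lie at a median of -1.14 on the left and 0.06 on the right, and ATF4 genes at 0.24 and -1.36.

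In RT101 colonies Dpt rose most, 46.6-fold, from 3.97 ± 0.12 (SD, n = 2) to 9.51 ± 0.04 (SD, n = 3; SE 0.11, adjusted p = 9.81e-13). Aspn, a small leucine-rich proteoglycan of the matrix, rose 45.5-fold (SE 0.20, adjusted p = 2.98e-10) and Mgp 43.9-fold (SE 0.18, adjusted p = 1.28e-10). Pi16 (log2 change 4.60), the chemokine gene Ccl8 (4.24), the siderophore-binding lipocalin gene Lcn2 (3.68), Islr (3.58), Prxl2a (3.53), Saa3 (3.51) and Ces1f (3.28), a carboxylesterase with close relatives, followed. The RT101 monolayer signals of Aspn (2.77) and Mgp (3.75) lay near the bottom of the scale, and that of Dpt (3.97) just above it. The largest falls were those of Car6, a secreted carbonic anhydrase (from 10.91 ± 0.09, n = 2, to 3.93 ± 0.04, n = 3, SD; log2 change -6.99, SE 0.13, adjusted p = 7.37e-13), and Calcb, a calcitonin gene-related peptide (-6.13, SE 0.12, adjusted p = 9.81e-13). The pentraxin gene Ptx3 (-4.63), Cth, an enzyme of cysteine synthesis (-4.44), the stretch-responsive gene Ankrd1 (-3.62) and Chac1, which degrades glutathione (-3.57), fell as well. Dach2 (-3.45), Taf7l (-3.25), the choline kinase gene Chka (-3.19) and Trib3 (-3.13) completed the 10. Of 12393 genes 4013 passed, 2102 up and 1911 down; 423 rose and 294 fell by at least 2-fold.

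Genes of the ATF4 and amino acid response fell in RT101 colonies, 20 of 24 with 2 up (median -1.36, adjusted p = 1.66e-14). Besides Chac1 and Trib3 they included Psph, an enzyme of serine synthesis (-2.43), and the hormone gene Fgf21 (-2.10). Cholesterol synthesis genes rose, 17 of 18 (median 1.003, adjusted p = 9.22e-12), with the isoprenoid enzyme genes Idi1 at 1.81 and Fdps at 1.44 and the sterol enzyme gene Nsdhl at 1.67. Lysosome and autophagy genes rose, 13 of 19 (median 0.52, adjusted p = 2.88e-05), with Lamp2, a lysosomal membrane protein, at 0.84, and the cathepsin D gene Ctsd at 0.80. Targets of YAP and TEAD, which respond to attachment and tension, fell, 10 of 17 with 1 up (median -0.44, adjusted p = 4.68e-05). After Ankrd1, the largest of these falls were in Ajuba (-2.45), Amotl2 (-2.13) and Ccn1 (-1.98). These 4 calls held with an estimated correlation (adjusted p 0.0191 to 0.0256). Adjusted over the list alone, ATF4 genes gave 2 up and 20 down, cholesterol genes 17 and 0, lysosome genes 13 and 0, and YAP/TEAD targets 1 and 12.

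By the preset test 5 more lists rose in RT101 colonies, and none of them passed with an estimated correlation. Collagen and matrix genes had 14 up and 3 down of 28 (adjusted p = 0.000558; adjusted p = 0.193 with an estimated correlation), with Col3a1, a fibrillar collagen chain, at 2.84. Fatty acid synthesis genes had 7 up and none down of 14 (adjusted p = 0.00771, then 0.0832), led by the desaturase gene Scd1 (1.45). Cytokine and NF-kB genes had 12 up and 3 down of 25 (adjusted p = 0.0243, then 0.107). FOXO and quiescence genes had 8 up and 3 down of 19 (adjusted p = 0.0243, then 0.115), led by the sestrin gene Sesn3 (1.53) and by Rbl2, a pocket protein of the cell cycle (1.53). Interferon-stimulated genes had 10 up and 1 down of 20 (adjusted p = 0.0265, then 0.107), led by the guanylate-binding protein gene Gbp2 (1.55). Adjusted over the list alone, the up and down counts were 14 and 3, 7 and 0, 12 and 4, 9 and 3, and 11 and 2. Mitosis genes did not pass (7 up, 4 down of 22; adjusted p = 0.493), nor did DNA replication genes (7 down of 22; adjusted p = 0.104) or ERK and immediate early genes (4 up, 6 down of 22; adjusted p = 0.278). Within the last list Myc fell (-2.09) and Fos rose (0.95). Markers of other cell types gave adjusted p of 0.875 (adipocyte, endothelial), 0.923 (skeletal muscle, melanocyte) and 0.982 (macrophage). Single genes of lists that did not pass also moved: the inhibitor-of-differentiation genes Id1 (2.39), Id3 (1.88) and Id2 (1.84) and the growth factor receptor gene Pdgfrb (3.07) rose, and the transcription factor gene Snai2 fell (-2.01). Fgf2 rose by 1.51 (adjusted p = 0.000165) and Fgfr1 by 0.71 (adjusted p = 0.00776), although the Fgfr1 call was lost when its probe sets were averaged (adjusted p = 0.0586) and without RT101 monolayer replicate 1 (0.0578). Ccnd1 (-0.34, adjusted p = 0.109), Cdkn1a (0.10, 0.467), Vim (0.10, 0.471) and Cdh1 (-0.04, 0.785) did not pass.

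**Figure D2:**
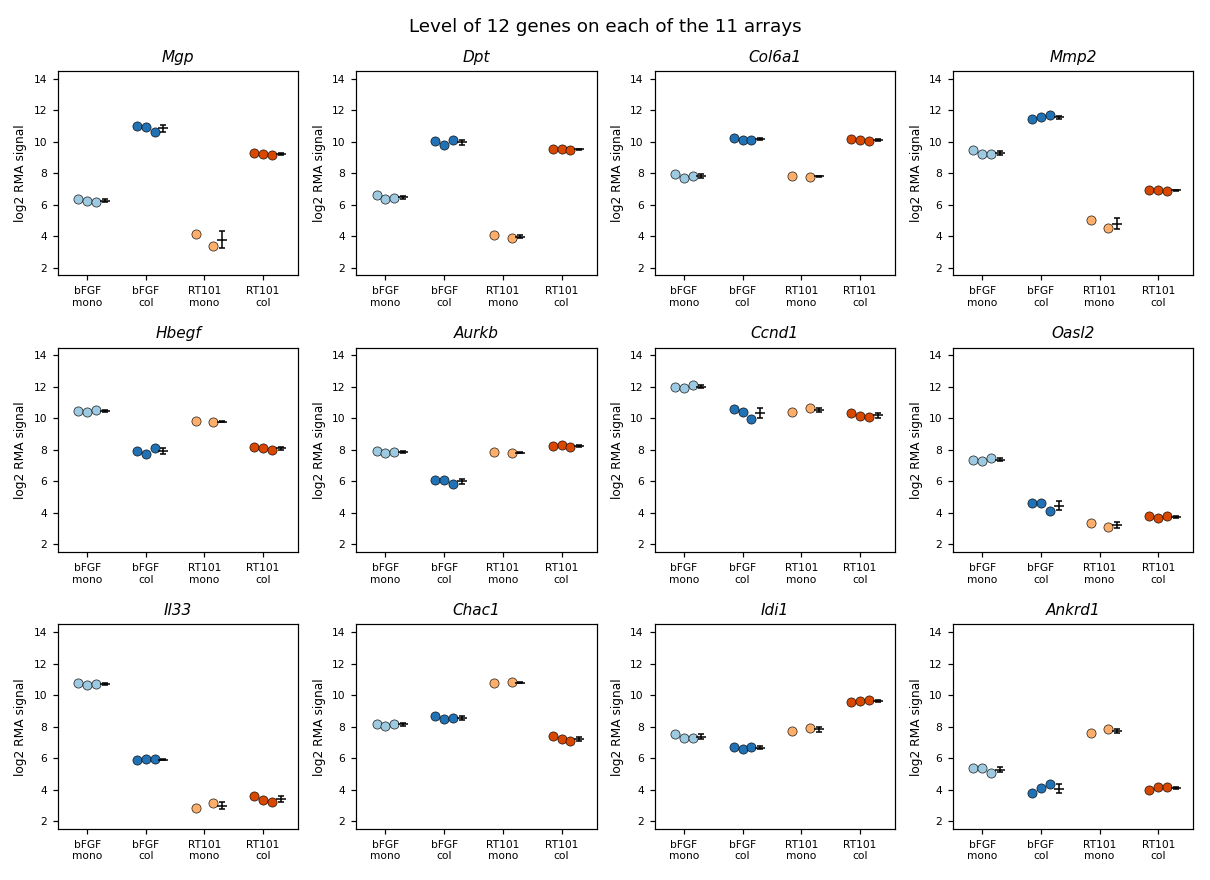
Points give the log2 signal of 12 named genes on each of the 11 arrays, by group (mono, monolayer; col, colonies); the bar beside each group is the mean with 1 SD. Col6a1 rises from about the same level in both lines (7.82 and 7.79 in monolayer, 10.15 and 10.09 in colonies), whereas Chac1 falls from 10.80 to 7.24 in RT101 and moves from 8.14 to 8.57 in bFGF-JB6.

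The overlap of both colony comparisons addressed the shared effects. Mgp, Saa3, Dpt, Ccl8, Col6a1, Mmp2, Gstm1 (a glutathione transferase) and Mgst1 (a microsomal one) led the genes that rose in both. Col6a1 rose 5.02-fold in bFGF-JB6 and 4.92-fold in RT101 colonies, and Mmp2 4.79-fold and 4.38-fold. For neither gene was a difference between the lines' colony changes called (interaction adjusted p = 0.897 and 0.67). The level of Mmp2 still differed, at 6.88 to 6.94 in RT101 colonies against 11.45 to 11.66 in bFGF-JB6 colonies. Genes that fell in both were led by Hbegf (-2.56 and -1.68), Msln (-2.79 and -1.30), the small GTPase gene Rras2 (-1.28 and -2.16), Nmt2 (-1.61 and -1.26), Steap1 (-1.23 and -2.03), the kinase gene Prkg2 (-1.22 and -1.39), the transcription factor gene Ets1 (-1.22 and -1.46) and Ankrd1 (-1.20 and -3.62). Together 1352 genes were called in the same direction. Of these, 706 rose, where independent lists would share 297 (odds ratio 4.47, 95% interval 4.00 to 5.01, two-sided Fisher's exact p = 1.01e-143), and 646 fell, where independent lists would share 291.6 (odds ratio 3.79, exact p = 3.78e-111). At 2-fold or more in each, 59 rose in both against 6.9 for independent lists, and 19 fell in both against 5.4. Opposite calls numbered 550, of which 197 rose in bFGF-JB6 and fell in RT101 (270 for independent lists) and 353 did the reverse (320.7). Changes correlated across genes at r = 0.217 (Spearman rho 0.208). The comparisons share no arrays but use the same estimate of each gene's spread, and genes are not independent replicates, so the exact p describes these lists only. The counts for independent lists also cover weak genes, which were seldom called. Among genes at or above the median level 3197 and 3634 were called, and 714 rose and 693 fell in both. Independent lists within those genes would share more than 297 and 291.6, so part of the excess reflects signal level.

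**Figure D3:**
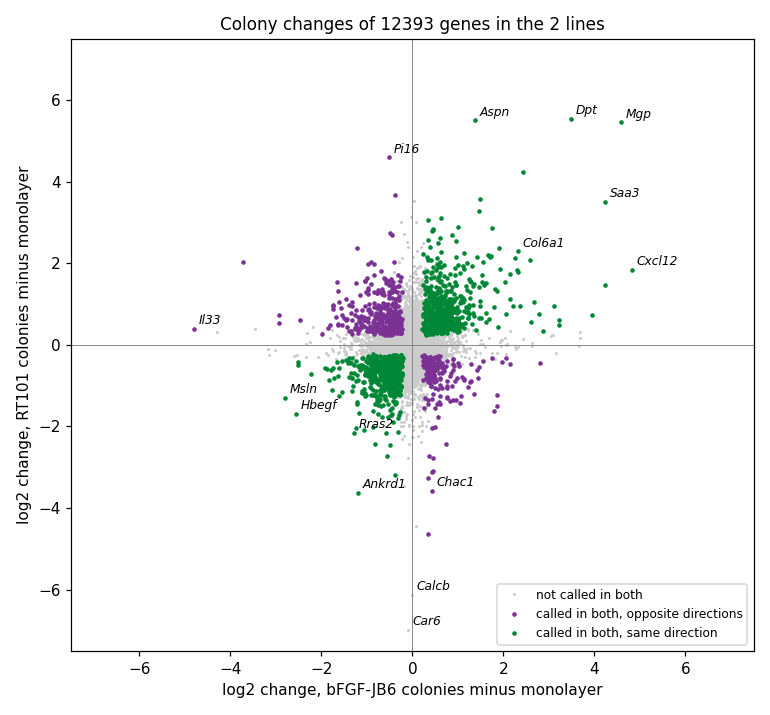
Each point is 1 of 12393 genes, placed by its log2 change in bFGF-JB6 colonies (x axis) and in RT101 colonies (y axis). Green points (1352) were called in both in the same direction and purple points (550) in opposite directions; Mgp and Dpt lie far up in both, while Car6 and Calcb fell in RT101 to 3.93 and 3.07, close to their bFGF-JB6 monolayer signals (4.08 and 2.90).

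The difference between the lines' colony changes was tested directly. Ifi27l2a, Il33, Pi16, Tslp, Aspn, Lcn2, Mndal and Rtp4 had the most positive differences, from 5.75 to 3.66 on the log2 scale, and Car6, Calcb, Ptx3, Cth, Chac1, Gsta3, Taf7l and Trib3 the most negative, from -6.89 to -3.55. The positive group mixed genes that fell in bFGF-JB6 (Il33, Tslp, Rtp4) with genes that rose in RT101 (Pi16, Aspn, Lcn2). On the linear scale the RT101 rise covered 81.66% of the gap to bFGF-JB6 colonies for Pi16 and 30.91% for Lcn2. The differences of Pi16 and Lcn2 thus partly restate those between the monolayers. Aspn, at 2560.08%, rose far beyond its bFGF-JB6 colony level. Il33 (2.98) lay near the bottom of the scale in RT101 monolayers and could hardly fall there, Rtp4 (4.27) lay above it and Tslp (8.42) far above it. Calcb (2.90) and Taf7l (2.71) lay near the bottom in bFGF-JB6 monolayers, and Ptx3 (4.00) and Car6 (4.08) just above it, so these 4 differences largely restate those between the monolayers. Among the lists, 20 of 22 mitosis genes, all 18 cholesterol synthesis genes and 13 of 20 interferon-stimulated genes were higher in the RT101 change than in the bFGF-JB6 change, by medians of 1.06 (adjusted p = 1.64e-16), 1.13 (1.60e-13) and 1.42 (9.55e-07). Interferon-stimulated genes such as Oasl2 (3.22) and Gbp3 (3.08) lay near the bottom of the scale in RT101 monolayers and could hardly fall there, so this list difference partly restates that between the monolayers. Genes of the ATF4 response were lower, 21 of 24 (median -1.72, adjusted p = 1.57e-19), as were 7 of 17 YAP/TEAD targets (median -0.52, adjusted p = 0.000748). In RT101 against bFGF-JB6 monolayers, 7 YAP/TEAD targets stood higher and 2 lower, and the list did not pass (camera adjusted p = 0.0544). Between colonies 6 stood higher and 4 lower (camera adjusted p = 0.971), so the YAP/TEAD difference may partly restate that between the monolayers. DNA replication genes (11 of 22, median 0.45, adjusted p = 4.45e-05) and ERK and immediate early genes (11 of 22, median 0.58, adjusted p = 0.00108) were higher. These 7 calls held with an estimated correlation (adjusted p 0.00862 to 0.0319). Adjusted over the list alone, 20 mitosis, 18 cholesterol, 13 interferon-stimulated, 11 replication and 12 ERK genes were higher, and 22 ATF4 and 8 YAP/TEAD genes lower. Against the direction of their list, 2 interferon-stimulated and 2 ERK genes were lower by either adjustment, and none in the other 5 lists. Mesenchymal markers (8 up, 1 down of 19; adjusted p = 0.0305) and integrin and adhesion genes (9 up, 3 down of 20; adjusted p = 0.0347) passed by the preset test alone (adjusted p = 0.111 and 0.209 with an estimated correlation), and the integrin call was lost without the 2 arrays of raised 3' signal (adjusted p = 0.109) and without bFGF-JB6 colonies replicate 3 (0.0678). Both calls were also lost under cyclic loess (adjusted p = 0.0732 and 0.0751). Lysosome genes, raised in both lines, had a median difference of -0.04 (3 higher, 6 lower of 19, adjusted p = 0.607). Collagen and matrix genes had one of -0.01 (7 higher, 5 lower of 28, adjusted p = 0.707). Single matrix genes differed in both directions, from -2.829 to 2.761, so the median does not show a response common to all members. In total 3430 genes passed, 1856 positive and 1574 negative; 582 and 386 of these differed by at least 2-fold. They included 419 of the 1352 genes called in the same direction in both colony comparisons, 933 of the 1740 called in bFGF-JB6 alone and 1388 of the 2111 called in RT101 alone. For the other genes called in one line alone, no difference between the lines was shown.

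Monolayers of the lines were compared next. Car6, Calcb and Ptx3 were 114-fold, 78.4-fold and 42.9-fold higher in RT101 monolayers, and Dach2 (log2 difference 5.38), Syce2 (5.11), Prss23 (4.00), the proteoglycan gene Ogn (3.87), the adrenomedullin gene Adm (3.84), Slc6a15 (3.78) and Cth (3.72) also ranked highest. Il33 was 213-fold lower (log2 difference -7.73, SE 0.12, adjusted p = 4.17e-14) and the calgranulin gene S100a8 204-fold lower (-7.67, SE 0.12, adjusted p = 4.17e-14). Aldh3a1 (-6.45), the cadherin gene Cdh11 (-6.45), the stromelysin gene Mmp3 (-6.37), Ces1f (-6.17), Glipr1 (-6.14), the protease inhibitor gene Slpi (-6.14), the decorin gene Dcn (-6.12) and Mgst1 (-6.03) were also lower in RT101. ATF4 and amino acid response genes stood higher in RT101 monolayers (18 of 24, median 1.40, adjusted p = 3.2e-07). Interferon-stimulated genes (15 of 20, median -1.72, adjusted p = 3.2e-07), lysosome genes (14 of 19, median -0.85, adjusted p = 2.05e-05) and matrix proteases (12 of 18, median -1.27, adjusted p = 2.05e-05) stood lower. These 4 held with an estimated correlation (adjusted p 0.0153 to 0.0399). Adjusted over the list alone, the counts higher and lower were 19 and 3, 3 and 15, 1 and 14, and 3 and 12. By the preset test alone, mitosis (13 higher, 1 lower of 22; adjusted p = 0.0118), DNA replication (11 and 0 of 22; 0.0118), hypoxia (10 and 2 of 17; 0.013) and cholesterol synthesis genes (10 and 2 of 18; 0.0343) stood higher in RT101. ERK and immediate early genes (5 and 12 of 22; adjusted p = 0.0112) and collagen and matrix genes (5 and 13 of 28; 0.0496) stood lower. For these 6 lists the adjusted p with an estimated correlation ran from 0.0691 to 0.408. The cholesterol call was lost without RT101 monolayer replicate 2 (adjusted p = 0.053). The matrix call was lost without that array (0.053), without bFGF-JB6 monolayer replicate 1 (0.0546), without bFGF-JB6 colonies replicate 1 (0.052) or 2 (0.0522), and under cyclic loess (0.0685). In total 5504 of 12393 genes differed, 2881 higher and 2623 lower in RT101; at 2-fold or more, 660 were higher and 858 lower. The bFGF-JB6 monolayers were labelled as treated, without dose or time, and RT101 received no growth factor, so this contrast does not separate line from treatment.

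Between colonies of the lines, mitosis genes stood higher in RT101, all 22 of 22 (median 1.85, adjusted p = 3.19e-17), as did 19 of 22 DNA replication genes (median 0.83, adjusted p = 1.21e-08) and all 18 cholesterol synthesis genes (median 1.61, adjusted p = 2.58e-13). Lysosome genes (15 of 19, median -0.85, adjusted p = 9.83e-07) and matrix proteases (13 of 18, median -1.14, adjusted p = 1.45e-07) stood lower, as in monolayers. These 5 held with an estimated correlation (adjusted p 0.0139 to 0.0153). The counts higher and lower, adjusted over the list alone, were 22 and 0, 19 and 0, 18 and 0, 1 and 17, and 2 and 14. By the preset test alone, ribosomal protein genes stood higher (7 higher, 0 lower of 11; adjusted p = 0.0155). Lower were ATF4 response (4 and 11 of 24; 0.0236), interferon-stimulated (2 and 9 of 20; 0.0236), p53 target (2 and 10 of 17; 0.0271), collagen and matrix (7 and 13 of 28; 0.0325) and FGF ligand and receptor genes (1 and 5 of 17; 0.044). For these 6 the adjusted p with an estimated correlation ran from 0.0895 to 0.474. Under cyclic loess the ribosomal call was lost and its median went from 0.257 to 0.119 (adjusted p = 0.159). The FGF call was lost under cyclic loess (adjusted p = 0.0614), without bFGF-JB6 colonies replicate 2 (0.0602) and without RT101 colonies replicate 2 (0.0518) or 3 (0.0514). Syce2 (5.39), Olfm1 (5.19), Ogn (4.94), Aspn (4.05), Adm (3.58), Cav1 (3.53), Myzap (3.45), Bnc1 (3.44), the sterol carrier gene Stard4 (3.25) and Col8a1 (3.17) were highest in RT101 colonies. Lowest were S100a8 (-8.12), the galectin-3 gene Lgals3 (-7.25), Cdh11 (-6.82), Glipr1 (-6.66), Aldh3a1 (-6.62), the cathepsin gene Ctsz (-6.15), Prl8a9 (-5.85), Mycn (-5.72), Slpi (-5.66) and Mmp13 (-5.57). S100a8 read 11.61 ± 0.10 in bFGF-JB6 colonies and 3.50 ± 0.21 in RT101 colonies (SD, n = 3 each), the latter near the bottom of the scale. In total 5372 genes differed, 2809 higher and 2563 lower in RT101 colonies; at 2-fold or more, 630 were higher and 617 lower.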

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

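Of the tests in this part, the fit without the 2 arrays with raised 3' signal, the position of ATF4-response genes against all other groups, the synthetase genes and the shares of mixed-in cells that were needed and seen were chosen only after the results were seen. Each item below was picked out because the RT101 colony change differed from the bFGF-JB6 colony change in the interaction test at an adjusted p of 0.05; values are the difference on the log2 scale. The count of such genes was 3430. List medians were -1.72 for the ATF4 and amino acid response, 1.06 for mitosis, 1.13 for cholesterol synthesis, 1.42 for interferon-stimulated genes, 0.45 for DNA replication, -0.52 for YAP/TEAD targets and 0.58 for ERK and immediate early genes. Mesenchymal markers (0.32) and integrins (0.46) passed by the preset correlation and were lost with an estimated one (adjusted p 0.111 and 0.209). Positive differences were those of Ifi27l2a (5.75), Il33 (5.2), Pi16 (5.12), Tslp (4.60), Aspn (4.14), Lcn2 (4.07), Mndal (3.83) and Rtp4 (3.66). Negative ones were those of Car6 (-6.89), Calcb (-6.11), Ptx3 (-4.96), Cth (-4.52), Chac1 (-4.00), Gsta3 (-3.69), Taf7l (-3.60) and Trib3 (-3.55). Il33 lay near the bottom of the scale in RT101 monolayers, and Calcb and Taf7l in bFGF-JB6 monolayers, which limits how these differences can be read. Outlying arrays were not sought within groups, since none held 4 arrays.

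All 22 mitosis genes fell in bFGF-JB6 colonies, whereas in RT101 colonies 7 rose and 4 fell (difference between lines, adjusted p = 1.64e-16). Uneven RNA quality as the whole cause is argued against, since the median was -1.142 without the 2 arrays with raised 3' signal. The fall did not hinge on the normalization, with a median still at -1.118 under the one that gave the smaller fall. This could not decide on scaling, since RMA had already brought the arrays to a common distribution. The bFGF-JB6 array medians ran from 5.86 to 5.95, so median centring could hardly move the list. Also open is biology the design names but does not part: the lines, the growth factor, and the growth state and density of the monolayers. The labels do not give that growth state or density.

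ATF4 and amino acid response genes fell in RT101 colonies (median -1.36). A single odd RT101 monolayer array is argued against, since the median stayed at -1.359 or lower whichever of the 2 arrays was left out. Mixing with bFGF-JB6 cells is argued against: the 20 members that fell would need a median share of 112.7%, over 100% for 13 of them, while transcripts that such cells would bring appeared at a median of 0.15% of their bFGF-JB6 level; that 5 of the 20 lay over 0.5 below all 3 other groups decided nothing, as its bound was set after the values were seen and met exactly. Aminoacyl-tRNA synthetase genes, known targets of ATF4 that are not on the list, had a median of -0.915. A lower ATF4-type response as a whole would give such a fall. But this family and its bound were also chosen after the results were seen, so its fall cannot decide on that response. Genes on the ATF4 and amino acid response list stood higher in RT101 than in bFGF-JB6 monolayers. Their fall may therefore reflect the state of the RT101 monolayer as well as a change in the colonies. The labels give no culture time or medium change for the monolayers.

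RT101 colonies lay closer than RT101 monolayers did to bFGF-JB6 monolayers (root mean square log2 difference 0.649 against 0.772) and to bFGF-JB6 colonies (0.698 against 0.872). The same RT101 monolayer arrays enter both contrasts, which by itself gives a negative correlation across genes (-0.554 as measured). With these arrays kept apart the weaker correlation was -0.507, which argues against shared noise as the whole cause. Cells of bFGF-JB6 mixed into the RT101 colonies are argued against too: 37 transcripts abundant in bFGF-JB6 colonies and low in RT101 monolayers, such as S100a8 and Cdh11, appeared at a median of 0.15% of their bFGF-JB6 level, against the 68% that 285 genes that rose would need. Of the 37, 24 stood under 1% and the upper quartile was 3.1%. Pi16 (81.66%), Dpt (73.35%), Islr (51.27%) and Mgp (31.98%) stood far higher. An RT101 monolayer in an unusual state and a program common to both colony types stay open.

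For 3 arrays against 3 there are only 10 splits, too few for a share under 0.05. The real split of the bFGF-JB6 arrays called 3642 genes and the highest other split 0. For the colonies of both lines these were 5372 and 0. Every other split mixes the groups, which shrinks the contrast and adds the real difference to the spread. A low count there is likely whenever the groups differ, so these counts do not measure how often other splits would call genes without such a difference. For gene lists the real values were 10 and 11 and the highest of the other splits 9 and 7. Every other split passed lists at the preset correlation, at least 3 for bFGF-JB6 and at least 4 between colonies, although none called a gene. Mixed splits keep part of the real difference, so these counts give no rate of false list calls. They do leave lists that passed by the preset test alone less certain.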

How the results depend on the processing

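The only alternative here that was chosen after the data were seen is the fit without the 2 arrays of raised 3' signal, which called 3652 genes in bFGF-JB6 colonies, 4683 in RT101 colonies, 3682 for the difference between lines, 5671 between monolayers, 5698 between colonies and 1552 in both colony comparisons. Testing all probe sets separately called 5986, 6451, 5260, 9093, 8965 and 2113 in that order, since more features were tested. Requiring 2-fold left 432, 717, 968, 1518, 1247 and 78, by construction. The other settings kept every count of genes within 1.5 times. With an estimated correlation the lists that passed were 5 in bFGF-JB6 colonies, 4 in RT101 colonies, 4 between monolayers and 5 between colonies, against 10, 9, 10 and 11. Leaving out each array in turn gave 2995 to 3833, 3050 to 4548, 2666 to 3664, 4607 to 5898, 4770 to 5558 and 1062 to 1611 genes, with a lone RT101 monolayer array assumed to vary like the other groups; lists ranged from 9 to 12, 9 to 10, 8 to 9, 9 to 11 and 10 to 12 (difference between lines in the middle).

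Replicate numbers gave no clear sign of pairing: deviations of same-numbered bFGF-JB6 arrays from their group means correlated at 0.02, 0.08 and -0.25. Those of RT101 correlated at -0.25 and -0.15 by title. By description letter, which numbers the RT101 monolayers differently, they correlated at 0.15 and -0.13. Deviations within so small a group sum to 0 and differently numbered arrays were not compared, so whether samples were paired is not settled. With the titles as a replicate block the counts were 3073, 3165, 2650, 4774, 4835 and 967, and with the letters 3168, 3195, 2670, 4782, 4981 and 1029.

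Of 1440 list results under other settings 1385 kept their side of the threshold and direction, 42 were lost, 13 were gained and 0 reversed. Leaving out an array gave 1736 of 1760. Most of these results were for lists that had not passed in the main fit and so could not be lost. There 10, 9, 9, 10 and 11 of 32 lists had passed in the 5 contrasts. Of 3107 results for named genes 3051 held, 50 were lost, 5 gained and 1 reversed; leaving out an array gave 3466 of 3531. The reversed value was Higd1a in bFGF-JB6 colonies, at 0.21 (adjusted p = 0.13) with probe sets averaged, because its 2 other probe sets went the other way. Median centring moved the share of RT101 colony calls that rose from 52.4% to 44.6%, and the median difference of all genes between monolayers from 0.05 to 0.10, so small list medians are read against that shift. It also turned the majority among genes called in both colony comparisons (612 up, 727 down) and for the difference between lines (1665 positive, 1716 negative). Cyclic loess turned it between monolayers (2677 higher, 2875 lower in RT101) and between colonies (2681 and 2794). Which direction held more calls thus depended on the scaling. Signals near the bottom of the scale limit what can be said of weak genes.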

Other observations

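The gene families below, 10 in all, and the members named were chosen after the data were seen, and were tested with camera within each contrast. Aminoacyl-tRNA synthetase genes, which charge transfer RNA, fell in RT101 colonies, 16 of 18 with 1 up (median -0.92, adjusted p = 3.08e-11; 0.0342 with an estimated correlation), among them Nars (-1.28), Gars (-1.24) and Wars (-1.17). In bFGF-JB6 colonies 7 fell and 1 rose (adjusted p = 0.0852). The difference between lines had a median of -0.92 (adjusted p = 1.73e-07; 0.0967 with an estimated correlation). Glutathione S-transferase genes rose in RT101 colonies, 11 of 21 with none down (median 0.27, adjusted p = 5.65e-05; 0.0342 with an estimated correlation), and in bFGF-JB6 colonies 9 rose and 3 fell (adjusted p = 0.0267; 0.184). Gstm1 rose by 2.07 and 2.59 in these, and Gstm2 by 1.10 and 1.14, although members of this family resemble each other. Beta protocadherin genes, a cluster of cell-adhesion genes with similar sequences, rose in RT101 colonies, 8 of 22 with none down (median 0.25, adjusted p = 0.00144; 0.0997), led by Pcdhb20 (2.61), and in bFGF-JB6 colonies, 7 of 22 (adjusted p = 0.0153; 0.184), led by Pcdhb9 (3.22). Most members lay near the bottom of the scale.

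Proteasome subunit genes fell slightly in bFGF-JB6 colonies, 14 of 38 with none up (median -0.16, adjusted p = 0.000947; 0.194 with an estimated correlation), while in RT101 colonies 4 rose and 5 fell (adjusted p = 0.808). Their difference between lines had a median of 0.22 (8 up, none down; adjusted p = 0.0255; 0.612). S100 genes, which encode calcium-binding proteins, rose in RT101 colonies, 5 of 11 (adjusted p = 0.0409; 0.0997), while in bFGF-JB6 colonies 5 fell and 2 rose (adjusted p = 0.0852); S100a13 was at 1.52 and -0.58 and S100a10 at 0.92 and -0.84. The difference between lines passed for S100 genes by the preset correlation (median 0.60, adjusted p = 0.0198; 0.0967 with an estimated correlation). Complement genes rose in bFGF-JB6 colonies, 4 of 11 (adjusted p = 0.0193; 0.184), and in RT101 colonies 2 rose and 2 fell (adjusted p = 0.808), with no difference between lines shown (median -0.119, 1 up, 2 down; adjusted p = 0.473, then 0.612); the complement protease genes C1s1 and C1ra were the members that rose in both, by 1.75 and 1.62 in bFGF-JB6 and by 2.87 and 1.51 in RT101. Under median centring and cyclic loess the medians of the families given a direction here kept their sign. MHC class I genes, cathepsins, aldo-keto reductases with aldehyde dehydrogenases, and chaperonins with Hsp40 genes did not pass in either colony comparison.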
